A study of Homo sapiens with 6 samples.

How the data were processed

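RNA of 3 human oral cancer lines, HSC3, HSC4 and SAS, each grown in DMEM and in HPLM, was measured in 6 libraries. Per the labels' protocols, polyadenylated RNA was selected, libraries were strand-specific and sequencing was done on a DNBSEQ instrument. Per the submitters' processing notes, reads were checked with FastQC and quantified with kallisto against hg38. The tool versions and the annotation release are not given in the sources used here, nor is whether strand was used in quantification, so a gene and an overlapping antisense gene may share reads.

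The authors deposited 1 table of expected counts per transcript, in a form its name calls scaled TPM. Such values are transcript abundances scaled up to the size of the library, so a value is an estimated count corrected for transcript length and not a number of reads. Short transcripts therefore have larger values, and long ones smaller values, than their reads, and the precision that the test takes from a count is approximate. For that reason no counting interval is given. The columns were matched to samples by the cell line, and for HPLM the medium, in their names, and 0 columns of per-sample values were left unused. The columns taken for DMEM carry the name of the line, no medium, and an ending that the labels do not explain.

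The table held 161149 rows for 159837 transcripts. The 1312 repeated rows, which came to between 0.21% and 0.27% of a library, were counted once. The 6878 transcripts without a gene symbol, between 0.362% and 0.479% of a library, were left out. The remaining 152959 transcripts were summed to 27852 symbols, of which 20488 were above 0 in some library, and the sums were rounded to whole numbers. Library totals after these steps lay between 17715962 and 20171750. Of the transcripts with a symbol, 95.3% were in GENCODE 29 (GRCh38, the build the submitters name), which gave positions, gene types and transcript lengths through transcript identifiers.

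Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the medium as group (minimum count of 10, minimum total of 15), which left 13236, and libraries were scaled by TMM. The edgeR quasi-likelihood test was fitted with cell line and medium as terms, leaving 2 residual degrees of freedom and an estimated 4 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05. Standard errors were computed as the absolute log2 fold change over the square root of the F statistic. Lines were compared in the same fit. Ratios per line were differences of log2 CPM with a prior count of 2.

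Each line gave 1 library per medium, so the line pairs the libraries. The deviations from the mean of the medium correlated across genes at 0.779 for HSC3, 0.792 for HSC4 and 0.805 for SAS between the libraries of 1 line, and the highest value between a DMEM library and an HPLM library of another line was −0.335. Subtracting that mean draws values between lines below 0, so their sign says nothing. Without it, Spearman's rho was 0.983, 0.985 and 0.984 within a line. Between a DMEM and an HPLM library of different lines it was at most 0.917.

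Before the data were examined, 37 gene lists were fixed, with 692 entries, of which 685 were in the table and 619 were tested. The 7 entries outside the table were not analysed here. Of the lists, 36 had at least 2 tested genes. The list of globins did not and gave no result. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. A list's median in 1 line was also given as a percentile among 10000 random lists of the same size matched on mean expression, as a description of those libraries.

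The rule for named genes was fixed at the same time. It took up to 6 genes per direction with the largest change among called genes of 1 direction in all lines and a mean CPM of 5 or more. Places left were filled by smallest p among uncalled genes that met the same limits of direction and CPM. It took from each list the 2 members with the smallest p and a mean CPM of 1 or more, or 4 where the list passed, and 8 genes whatever their values: TXNIP, ASNS, HMGCS1, ASS1, CYP1A1, UMPS, CDH1 and VIM. For each line it took the 4 genes highest above both other lines, among genes called in both contrasts and with a mean CPM of 5 or more there. XIST and Y-linked genes were not named, and some genes that the rule took are not reported here. CSF3, HSD11B1 and the other genes 2-fold changed in all lines and genes named with a call count were chosen after their values were seen.

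The tests were checked on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds. For the medium comparison (12991 genes tested) 88.1% of the 2-fold, 100% of the 4-fold and 100% of the 8-fold changes were called, with 14 false calls. With a spread that varied between genes as the fit estimated (12934 genes tested) the shares were 40.3%, 89.6% and 96.9%, with 9 false calls. For HSC4 against HSC3 (13031 genes tested) they were 80.6%, 100% and 100%, with 18 false calls. Among 36 simulated lists of 20 genes (12998 genes tested), camera with a preset correlation called the 1 list raised 1.5-fold and 0 of the 35 unchanged lists, and with an estimated correlation it called 0 of the 36. The simulated genes were independent of each other, so this says nothing of false list calls among correlated genes; in the data the estimated correlation within a list reached 0.79, and the 3 other splits that part every pair called 12, 8 and 12 lists by camera with a preset correlation.

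The alternatives were the fit without the line, other scalings, other filters, DESeq2, limma-trend, limma-voom, robust quasi-likelihood, other thresholds and leaving out each line or library. Leaving out mitochondrial-encoded genes, keeping protein-coding genes alone, and leaving out each line from the values per line were chosen after seeing the data.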

Results

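Poly(A) RNA was sequenced from HSC3, HSC4 and SAS, established human lines of oral squamous cell carcinoma, each grown in 2 media. DMEM is a standard culture medium with nutrients at levels unlike those of blood, and HPLM is a medium composed to resemble human plasma. Both were supplemented with heat-inactivated fetal bovine serum. There were 6 libraries, 3 per medium and 1 for each line and medium, so the 3 lines stand in for replicates. Estimated counts summed to 19665471 in DMEM and 20171750 in HPLM for HSC3, to 19210908 and 17715962 for HSC4, and to 18750890 and 20123287 for SAS. P-values measure the spread of the response over these 3 lines, and within a line the difference between media has no replicate check.

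The first comparison asked which genes differ between cells grown in HPLM and in DMEM, with the cell line as a block. XAB2, which encodes a splicing and DNA repair factor, rose in HPLM by a log2 fold change of 2.94 ± 0.18 (SE, 3 lines; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0478). Its CPM was 1.94 in DMEM and 11.5 in HPLM in HSC3, 1.62 and 13.1 in HSC4, and 3.23 and 29.4 in SAS. The gene lies on chromosome 19, from 7619525 to 7629565 on the minus strand (GENCODE 29, GRCh38), and 1 of its 4 transcripts in the table carried the difference. XAB2 was the single gene of 13236 tested past the threshold, with 1 higher and 0 lower. At an unadjusted p under 0.05 edgeR counted 1339 genes, 737 higher and 602 lower in HPLM, while DESeq2 called 127 genes, limma-voom 9 and limma-trend 0. The Wald test of DESeq2 takes the estimated spread as known and does not count the few residual degrees of freedom. With 3 lines its p-values can therefore be too small, and its calls are no check of the edgeR result. The XAB2 call ended with upper-quartile scaling (edgeR adjusted p = 0.0626), without the low-count filter (0.0618), with limma-trend (0.0535), without HSC4 (0.103), without SAS (0.187) and without the line as block (1), and without HSC3 edgeR called 4 genes, PI3, XAB2, S100A8 and LCN2.

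The 5 next genes on the higher side, named by smallest p at a mean CPM of 5 or more and not past the edgeR threshold, were acute-phase, calprotectin, keratin and growth factor-binding genes. DESeq2 called all 5, from an adjusted p of 8.43e-38 for SAA1 to 6.9e-06 for KRT6B, and limma-voom called SAA1, SAA2, S100A8 and KRT6B (adjusted p from 0.0362 to 0.0423). SAA1, which encodes the acute-phase protein serum amyloid A1, had a log2 fold change of 2.65 ± 0.22 (SE, edgeR adjusted p = 0.121) and a CPM of 132 in DMEM against 971 in HPLM in HSC3. Its neighbour SAA2 had 3.15 ± 0.35 (edgeR adjusted p = 0.155), and because these paralogs are nearly identical the split of reads between them is uncertain. They lie on chromosome 11, SAA1 from 18266174 to 18269977 and SAA2 from 18239223 to 18248643 (GENCODE 29, GRCh38). S100A8, a subunit of the antimicrobial protein calprotectin, had 2.18 ± 0.20 and KRT6B, a keratin of activated epithelium, had 1.78 ± 0.17 (edgeR adjusted p = 0.121 for each). KRT6B lay under 1 CPM in both SAS libraries and shares reads with other keratin 6 genes. IGFBP3, which encodes a binding protein of insulin-like growth factors, had 2.0 ± 0.22 (edgeR adjusted p = 0.155). The rule took only genes of 1 direction in all lines, so all 5 were higher in HPLM in each of the 3 lines by selection.

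On the lower side no gene passed the edgeR test. The 6 named had the smallest p among genes with a mean CPM of 5 or more that were lower in all 3 lines. DESeq2 called all 6, from an adjusted p of 1.97e-17 for ALPP to 9.24e-06 for IGFL1P1, and limma-voom called IFNWP19 and NMRAL2P (adjusted p = 0.0423 for each). Both tools also called the pseudogenes RPL39P36 and MTCO1P3 (limma-voom adjusted p = 0.0362 for each), which lay under that CPM and were named after their values were seen. RPL39P36 had 3.56, 3.01 and 6.68 CPM in DMEM in HSC3, HSC4 and SAS, MTCO1P3 had 2.2, 2.1 and 2.21, and both were at 0 in all 3 HPLM libraries. ALPP, the placental alkaline phosphatase gene on chromosome 2 (232378534 to 232382889), had a log2 fold change of −3.12 ± 0.35 (SE, edgeR adjusted p = 0.155), with a CPM of 101 in DMEM and 18.8 in HPLM in HSC4. UGT1A6, a glucuronosyltransferase gene that shares exons with its relatives, had −1.82 ± 0.23 (edgeR adjusted p = 0.197). F2R, the gene of a thrombin receptor, had −1.31 ± 0.18 (edgeR adjusted p = 0.253). The other 3 of the 6 were pseudogenes, whose reads cannot be parted with certainty from those of related genes: IFNWP19 at −1.06 ± 0.10, NMRAL2P at −2.10 ± 0.23 and IGFL1P1 at −2.05 ± 0.24 (edgeR adjusted p = 0.121, 0.155 and 0.170).

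**Figure D1:**
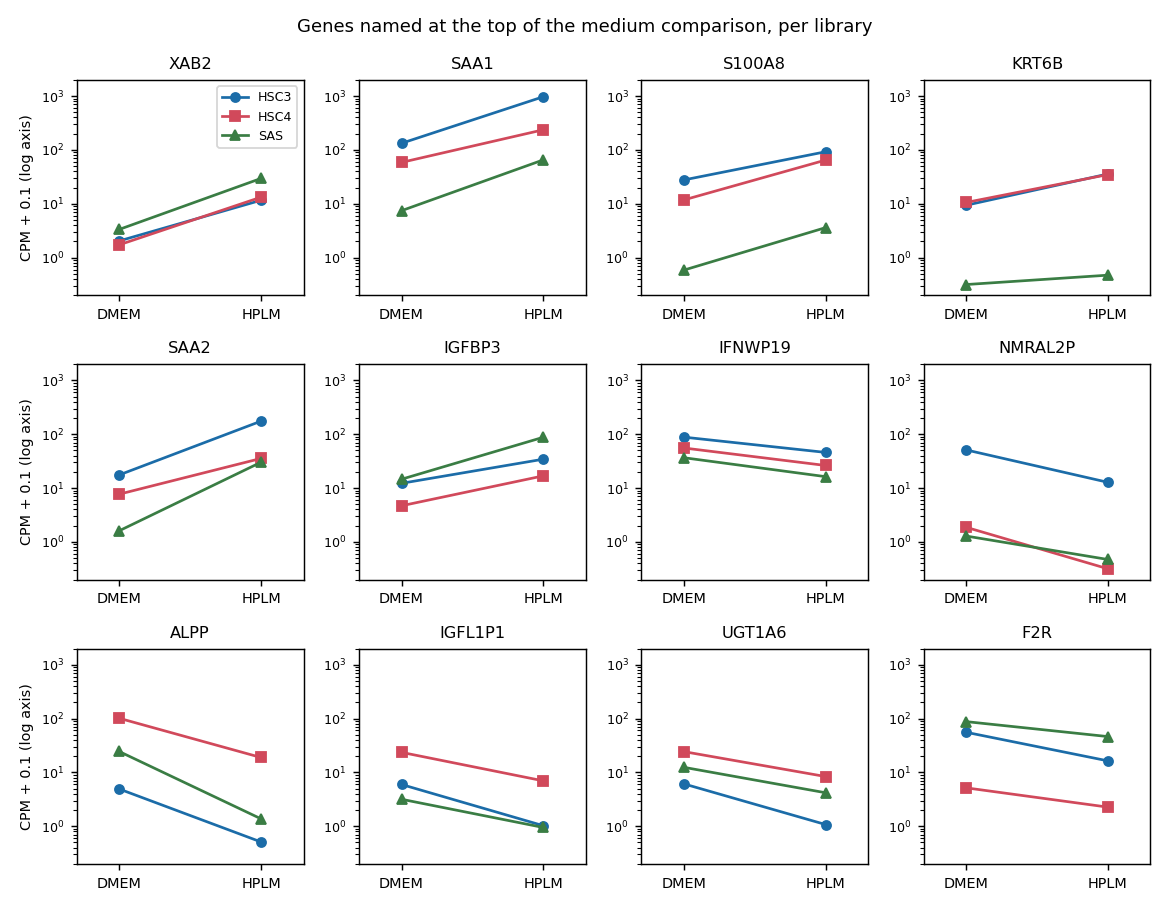
CPM of the 12 genes named first in the medium comparison (log vertical axis, 0.1 added), with 1 point per library and a line joining the DMEM and HPLM libraries of each cell line. Only genes of 1 direction in the 3 lines were eligible, and by edgeR XAB2 alone passed the threshold.

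Genes of inflammation and of keratinocyte differentiation stood highest among the 36 gene lists tested. The list of cytokines and other NF-kB targets rose in HPLM, with a median log2 fold change of 0.80 over 20 tested genes, all 20 of them positive and 14 higher in every line (camera adjusted p = 1.33e-18, and adjusted p = 0.45 with an estimated correlation). Adjusted over the list alone 11 of the 20 passed, all higher, against 0 adjusted over all genes by edgeR, where 11 had an unadjusted p under 0.05; XAB2 is in none of the lists, so this 0 holds for each list. Among them were the neutrophil-attracting chemokine genes CXCL1 (3.07 ± 0.72, SE) and CXCL2 (2.06 ± 0.38), the chemokine gene CCL20 (3.04 ± 0.73) and the cytokine gene IL1A (0.80 ± 0.13). The keratinocyte differentiation list rose with a median of 0.92 over 18 tested genes (camera adjusted p = 3.94e-19, and adjusted p = 0.44 with an estimated correlation), and 9 passed adjusted over the list alone, all higher. It held 30 genes, and the differentiation markers KRT1, IVL, LORICRIN and FLG were too low to test, at 2.34 CPM or less in any library. Of further tested members, named after their values were seen, KRT10 had −0.01 ± 0.11 and KRT13 0.23 ± 0.47. SPRR1B had 0.83 ± 0.21 and TGM1 0.83 ± 0.31. The members with the smallest p encode antimicrobial proteins and a protease inhibitor: S100A8, S100A9 (1.93 ± 0.32), the siderophore-binding LCN2 (2.69 ± 0.41) and PI3, or elafin (2.27 ± 0.35). Markers of leukocytes, 4 of them tested, had a median of 0.28 with all 4 positive (camera adjusted p = 0.113, limma's fry adjusted p = 0.23 in 1 direction and adjusted p = 0.035 for change in either direction), and among them CD68 had 0.27 ± 0.10 and CD74 0.30 ± 0.15.

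The lists of hypoxia-inducible and glycolytic genes were also higher in HPLM. The hypoxia list rose with a median log2 fold change of 0.49 over 22 genes (camera adjusted p = 1.16e-11, and adjusted p = 0.44 with an estimated correlation), and adjusted over the list alone 6 passed as higher and 1 as lower. The lower one, named after its values were seen, was the angiogenic growth factor gene VEGFA at −0.47 ± 0.13 (SE), lower in all 3 lines. ANGPTL4, a regulator of lipoprotein lipase, had 1.84 ± 0.24 (SE), the carbonic anhydrase gene CA9 1.65 ± 0.25, the mitophagy gene BNIP3 1.05 ± 0.18 and P4HA1, a collagen prolyl hydroxylase gene, 0.49 ± 0.12. The glycolysis list rose with a median of 0.16 over 22 genes (camera adjusted p = 0.000599, and adjusted p = 0.45 with an estimated correlation), and the enolase gene ENO2 (1.03 ± 0.19) was the 1 member to pass adjusted over the list alone. The glycolysis medians were 0.27 in HSC3, 0.16 in HSC4 and 0.00 in SAS, the last at percentile 29.6 of random lists matched on expression. LDHA had 0.39 ± 0.12, ALDOA 0.26 ± 0.09 and the lactate exporter gene SLC16A3 0.33 ± 0.10.

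The glucose-sensing list held targets of MondoA and MLXIP, the gene of MondoA itself (−0.05 ± 0.11, SE). It rose with a median of 0.44 over 5 genes (camera adjusted p = 0.0118, and adjusted p = 0.45 with an estimated correlation). The list medians were 0.00 in HSC3, 0.71 in HSC4 and 0.87 in SAS. ARRDC3 (0.95 ± 0.22) passed adjusted over the list alone. The list call ended without HSC4 (camera adjusted p = 0.125) and without SAS (0.0906). TXNIP, the best known of these targets, had 0.66 ± 0.34 with log2 ratios of −0.36 in HSC3, 0.76 in HSC4 and 1.74 in SAS. Its relative ARRDC4 had 0.44 ± 0.26, with a log2 ratio of −0.17 in HSC3, and KLF10 had 0.21 ± 0.11.

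Ribosomal protein genes rose by a small amount, with a median of 0.18 over 35 genes, 34 of them positive (camera adjusted p = 1.43e-06, and adjusted p = 0.45 with an estimated correlation). RPS9 had 0.33 ± 0.09 (SE), RPLP2 0.36 ± 0.10 and RPS18 0.28 ± 0.09, and 0 of the 35 passed the edgeR test adjusted over the list alone, with 8 at an unadjusted p under 0.05. The list medians were 0.07 in HSC3, 0.30 in HSC4 and 0.15 in SAS, at percentiles 39.8, 100 and 94.7 of random lists matched on expression. Nuclear genes of oxidative phosphorylation rose with a median of 0.12 over 32 genes, 30 of them positive (camera adjusted p = 0.000672, and adjusted p = 0.45 with an estimated correlation), and without HSC4 the call ended (camera adjusted p = 0.0913). The ATP synthase gene ATP5MC1 had 0.43 ± 0.09, NDUFA4 0.29 ± 0.09 and COX4I1 0.23 ± 0.08, and by edgeR 0 of the 32 passed adjusted over the list alone, with 6 at an unadjusted p under 0.05. With a trend with transcript length removed within each line, the mean of the line medians was 0.08 in place of 0.17 for the ribosomal protein list (camera adjusted p = 0.0269) and 0.07 in place of 0.11 for oxidative phosphorylation (camera adjusted p = 0.0422). The 13 genes encoded in mitochondrial DNA had a median of 0.07 (camera adjusted p = 0.59, and 0.00387 without HSC3, both at the preset correlation). With an estimated correlation of 0.75 and all lines the adjusted p was 0.85. These genes took from 12.03% to 15.15% of the counts of a library. MT-CO2 had 0.36 ± 0.11 and MT-ATP6 −0.17 ± 0.13.

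Immediate early genes rose with a median of 0.19 over 21 genes (camera adjusted p = 0.00298, and adjusted p = 0.45 with an estimated correlation), and 4 passed adjusted over the list alone, all higher. They were the phosphatase genes DUSP1 (1.04 ± 0.16, SE) and DUSP4 (0.43 ± 0.11), the transcription factor gene JUN (0.52 ± 0.10) and HBEGF, a ligand of the epidermal growth factor receptor (0.74 ± 0.18). That list call ended without HSC4 (camera adjusted p = 0.234). Genes of arginine and polyamine metabolism rose with a median of 0.10 over 17 genes (camera adjusted p = 0.0424, and adjusted p = 0.45 with an estimated correlation), and the call ended without HSC3 (camera adjusted p = 0.182), without HSC4 (0.304), without a scaling factor (0.0988), without the low-count filter (0.104) and with the length trend removed (0.0549). The polyamine genes SAT1 (0.90 ± 0.11) and ODC1 (0.50 ± 0.09) passed adjusted over the list alone, while SMS had 0.28 ± 0.10 and the argininosuccinate synthase gene ASS1 −0.36 ± 0.16.

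Genes of xenobiotic and oxidant defence were lower in HPLM. The NRF2 target list fell with a median log2 fold change of −0.42 over 21 genes, 20 of them negative (camera adjusted p = 2.81e-09, and adjusted p = 0.45 with an estimated correlation), and 7 passed adjusted over the list alone, all lower. The list medians were −1.01 in HSC3, −0.32 in HSC4 and −0.10 in SAS, and 3 of the 7, AKR1C1, AKR1C2 and AKR1C3, had higher values in HPLM in SAS. The quinone reductase gene NQO1 had −0.84 ± 0.15 (SE) and the ferritin gene FTH1 −0.71 ± 0.18. AKR1C1, which has near-identical relatives, had −1.56 ± 0.37, with log2 ratios of −1.98 in HSC3, −0.76 in HSC4 and 0.73 in SAS. In SAS AKR1C1 lay at 0.215 CPM in DMEM and 0.424 in HPLM, and AKR1C2 had a mean of 0.266 CPM. Ratios at such low levels are uncertain and show no opposite response of SAS. The aryl hydrocarbon receptor list fell with a median of −0.48 over 6 genes, all 6 negative (camera adjusted p = 0.000672, and adjusted p = 0.45 with an estimated correlation). CYP1A1, the cytochrome P450 gene that this receptor induces, had −2.51 ± 0.47, with log2 ratios of −3.46 in HSC3, −2.40 in HSC4 and −0.08 in SAS, and with the amino acid transporter gene SLC7A5 (−0.37 ± 0.09) it passed adjusted over the list alone. In SAS CYP1A1 was low in both media, at 1.13 CPM in DMEM and 1.06 in HPLM. NFE2L2 had −0.26 ± 0.10 and AHRR −0.58 ± 0.28.

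Interferon-stimulated genes fell with a median log2 fold change of −0.61 over 23 genes, 20 of them negative (camera adjusted p = 6.25e-08, and adjusted p = 0.52 with an estimated correlation). Without HSC4 the call ended (camera adjusted p = 0.15), and the list medians were 0.02 in HSC3, −1.33 in HSC4 and −0.33 in SAS. OASL had −1.83 ± 0.42 (SE), IFIT2 −1.15 ± 0.27, SAMD9 −0.71 ± 0.19 and IFI44 −1.27 ± 0.36, and by edgeR 0 of the 23 passed adjusted over the list alone, with 9 at an unadjusted p under 0.05. Genes of class I antigen presentation fell with a median of −0.19 over 14 genes (camera adjusted p = 0.00175, and adjusted p = 0.57 with an estimated correlation), a call that also ended without HSC4 (camera adjusted p = 0.439), with a median of 0.04 in HSC3. HLA-B had −0.34 ± 0.08, HLA-C −0.27 ± 0.09 and HLA-E −0.19 ± 0.09, and reads of these paralogs can be shared. By edgeR 0 of the 14 passed adjusted over the list alone, with 3 at an unadjusted p under 0.05.

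Lists of lipid synthesis and of the lysosome were lower by camera with the preset correlation. The fatty acid synthesis list fell with a median log2 fold change of −0.23 over 13 genes (camera adjusted p = 0.00126, and adjusted p = 0.45 with an estimated correlation), and SCD, the stearoyl-CoA desaturase gene, passed adjusted over the list alone at −1.98 ± 0.30 (SE). AACS had −0.35 ± 0.11, FADS2 −0.47 ± 0.17 and ME1 −0.29 ± 0.12. The medians of this list were −0.02 in HSC3, −0.17 in HSC4 and −0.12 in SAS. They lay at percentiles 38.8, 3.6 and 11.2 of random lists matched on expression. The cholesterol synthesis list fell with a median of −0.09 over 25 genes (camera adjusted p = 0.0115, and adjusted p = 0.72 with an estimated correlation), and its call ended without HSC4 (camera adjusted p = 0.0921) and without SAS (0.424), with a median of 0.08 in HSC3. INSIG1 had −0.52 ± 0.15, LSS −0.49 ± 0.17, CYP51A1 −0.29 ± 0.10, STARD4 −0.71 ± 0.26 and HMGCS1, the synthase of the pathway's start, −0.14 ± 0.11, and by edgeR 0 of the 25 passed adjusted over the list alone, with 4 at an unadjusted p under 0.05. The lysosome and autophagy list fell with a median of −0.13 over 21 genes, 17 of them negative (camera adjusted p = 0.00019, and adjusted p = 0.45 with an estimated correlation). The cathepsin genes CTSD (−0.83 ± 0.19) and CTSL (−0.38 ± 0.10), the cholesterol carrier gene NPC2 (−0.50 ± 0.13) and the channel gene MCOLN1 (−0.50 ± 0.14) had the smallest p, and by edgeR 0 of the 21 passed adjusted over the list alone, with 8 at an unadjusted p under 0.05.

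Replication-dependent histone genes fell with a median of −0.13 over 10 genes, 9 of them negative (camera adjusted p = 0.000672, and adjusted p = 0.45 with an estimated correlation). H1-2 (−1.11 ± 0.16, SE), H2AC6 (−1.27 ± 0.29) and H2BC5 (−0.90 ± 0.21) passed adjusted over the list alone, and H3C10 had −0.84 ± 0.48. The list medians were −1.13 in HSC3, −0.32 in HSC4 and, in the other direction, 0.10 in SAS. Most histone messages lack a poly(A) tail, so their level in poly(A) libraries also reflects selection. S-phase genes fell with a median of −0.09 over 22 genes, 18 of them negative (camera adjusted p = 0.0328, and adjusted p = 0.45 with an estimated correlation), a call that ended without HSC3 (camera adjusted p = 0.205) and without HSC4 (0.0921). MCM6 had −0.22 ± 0.09, PCNA −0.19 ± 0.08 and FEN1 −0.19 ± 0.09, and by edgeR 0 of the 22 passed adjusted over the list alone, with 2 at an unadjusted p under 0.05. The list of mitotic genes had a median of −0.07 over 24 genes (camera adjusted p = 0.38, and 0.000554 without HSC3, both at the preset correlation). With an estimated correlation of 0.6 and all lines the adjusted p was 0.84. BUB1 had −0.23 ± 0.09 and NUSAP1 0.22 ± 0.12.

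Of the 36 lists tested, 18 passed by camera with a preset correlation, 9 higher and 9 lower in HPLM. With an estimated correlation 0 passed, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.44. By fry in 1 direction 0 passed, with 7 at an unadjusted p under 0.05, and by fry for change in either direction 7 passed: keratinocyte differentiation, lysosome, histone, immediate early, leukocyte, basal epithelial and p53.

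**Figure D2:**
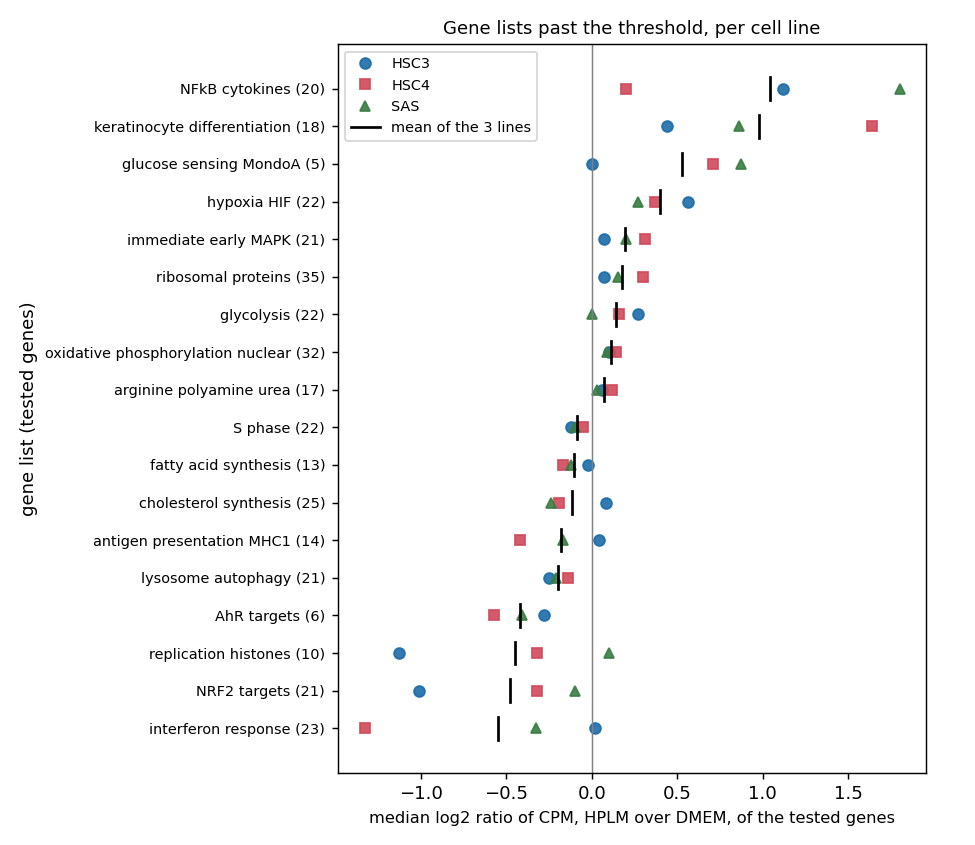
Median log2 ratio of CPM in HPLM over DMEM (horizontal axis) of the 18 gene lists past the camera threshold with a preset correlation, with 1 point per cell line, a black bar for the mean of the 3 lines and the number of tested genes in parentheses. The NF-kB list had medians of 1.12 in HSC3, 0.20 in HSC4 and 1.80 in SAS, and the interferon list 0.02, −1.33 and −0.33.

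Lists on the amino acid response and on nucleotide and ribosome synthesis did not pass by camera. Calls gained when a line was left out rest on the preset correlation. The ATF4 list had a median log2 fold change of −0.10 over 29 genes (camera adjusted p = 0.163, and adjusted p = 0.84 with an estimated correlation of 0.76). With a preset correlation it passed whenever 1 line was left out, with a mean of 0.33 without HSC3 (camera adjusted p = 0.00339), −0.30 without HSC4 (0.00214) and −0.41 without SAS (0.00124). Its members with the smallest p were ATF3, at 1.19 ± 0.26 (SE), and SLC7A5, at −0.37 ± 0.09. ASNS, the asparagine synthetase gene, had −0.54 ± 0.70, with log2 ratios of −2.90 in HSC3, 0.18 in HSC4 and 0.72 in SAS. The aminoacyl-tRNA synthetase list had −0.04 (camera adjusted p = 0.707), with FARSB at 0.41 ± 0.13 and WARS1 at −0.37 ± 0.12. Purine and pyrimidine synthesis genes had 0.08 (camera adjusted p = 0.239, and 0.0252 without SAS), with PRPS1 at 0.36 ± 0.10, ATIC at −0.19 ± 0.08 and UMPS, the enzyme that makes UMP, at 0.15 ± 0.14. Ribosome biogenesis genes under MYC had 0.03 (camera adjusted p = 0.227, and 0.00206 without SAS), with FBL at 0.18 ± 0.09.

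Lists of cell state and stress did not pass by camera either, and calls gained without a line again rest on the preset correlation. Basal epithelial genes had a median of −0.12 (camera adjusted p = 0.247, and 0.0088 without HSC4; fry adjusted p = 0.034 for change in either direction), with the integrin gene ITGA3 at −0.57 ± 0.12 (SE), and mesenchymal genes also had −0.12 (camera adjusted p = 0.707), with INHBA at 0.74 ± 0.22. CDH1, the gene of E-cadherin, had 0.17 ± 0.16 and VIM, the gene of vimentin, −0.24 ± 0.23. Targets of YAP and TGF-beta had 0.17 (camera adjusted p = 0.113, and 0.0217 without HSC3), with CCN1 at 0.37 ± 0.09. Stemness markers had −0.28 (camera adjusted p = 0.0561, and 0.0182 without SAS), with ALDH1A3 at −0.36 ± 0.12 and ABCG2 at −0.45 ± 0.17. The median was 0.00 for the unfolded protein response (camera adjusted p = 0.244; SDF2L1 at 0.31 ± 0.09, MANF at 0.25 ± 0.10) and −0.03 for heat shock genes (camera adjusted p = 0.542; HSPD1 at 0.18 ± 0.09, HSPA4L at −0.24 ± 0.12). It was 0.28 for metallothioneins (camera adjusted p = 0.104, and 0.0105 without SAS; MT2A at 0.40 ± 0.12, MT1E at 0.38 ± 0.12) and −0.08 for iron homeostasis (camera adjusted p = 0.284; TFRC at −0.25 ± 0.09). For p53 targets the median was 0.03, the mean −0.03 and the camera direction down (adjusted p = 0.638; fry adjusted p = 0.028 for change in either direction), with TNFRSF10B at 0.43 ± 0.10 and TP53I3 at −0.58 ± 0.16. Fibroblast markers had −0.11 over 3 genes (camera adjusted p = 0.542; ACTA2 at −0.39 ± 0.27, COL1A1 at 0.07 ± 0.24). Endothelial markers had −0.07 over 2 genes with a camera direction of up (adjusted p = 0.789; EGFL7 at 0.20 ± 0.13, ERG at −0.34 ± 0.54).

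The second comparison described each line on its own, as values without a test. Among 9816 genes with a mean CPM of 5 or more, 117 were at least 2-fold higher and 128 at least 2-fold lower in HPLM in HSC3, 111 and 61 in HSC4, and 165 and 71 in SAS. At least 2-fold higher in all 3 lines were 11 genes: XAB2, SAA1, SAA2, S100A8, S100A9, LCN2, PI3, IGFBP3, ANGPTL4, CSF3 and HSD11B1. At least 2-fold lower in all 3 lines were 5 genes: ALPP, SCD, UGT1A6, NMRAL2P and IGFL1P1. Independent lines with the same counts would give 0.022 and 0.0058 such genes if each gene were equally likely to change. That premise was not tested, so these values are not a test of the counts. CSF3, the gene of granulocyte colony-stimulating factor, had log2 ratios of 4.74 in HSC3, 2.06 in HSC4 and 2.64 in SAS, and HSD11B1, which regenerates cortisol, had 2.10, 1.82 and 1.48, with under 1 CPM in both media in HSC3 and HSC4. Other ratios also rest on low values, because the CPM limit is on the mean of all libraries. NMRAL2P lay at 1.77 CPM in DMEM and 0.216 in HPLM in HSC4, and at 1.185 and 0.371 in SAS. S100A8 lay at 0.485 and 3.5 in SAS, and CSF3 at 0.478 and 2.32 in HSC4. Without a line, 38 to 49 genes met the criterion in the remaining lines.

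The responses of the lines were compared across all tested genes. Pearson's r across genes was 0.131 for HSC3 and HSC4, 0.173 for HSC3 and SAS and 0.151 for HSC4 and SAS, with Spearman's rho of 0.151, 0.186 and 0.140. The mean r of 0.152 became 0.258 among genes with a mean CPM of 5 or more and 0.304 at 20 or more. These are correlations across genes, which are not independent replicates, so no p is given. The log2 ratio had the same sign in all 3 lines for 33.9% of genes, against 25% for independent signs. A technical difference between DMEM and HPLM libraries, if shared by the lines, would raise these correlations and this share. It was not tested.

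The third comparison was between the cell lines, with medium in the model and 2 libraries per line. MAGEA4 lay 6.31 ± 0.18 log2 units (SE) higher in HSC3 than in SAS and was at 0 in HSC4, TNNT3 lay 5.74 ± 0.47 higher in HSC4 than in SAS, and IGFL1 lay 6.84 ± 0.35 higher in SAS than in HSC4. HSC3 expressed the hydroxysteroid dehydrogenase genes AKR1C1 and AKR1C2 and the cancer-testis gene MAGEA4, HSC4 expressed C15orf48, C3orf14 and the troponin gene TNNT3, and SAS expressed IGFL1, HSD11B1, the keratin-associated KRTAP2-3 and the kallikrein gene KLK6, each far above the other lines. The edgeR F-test over lines called 7628 of 13236 genes, or 57.6%, at an adjusted p under 0.05. Between pairs of lines it called 4952 genes for HSC4 against HSC3 (2490 higher and 2462 lower in HSC4), 5213 for SAS against HSC3 (2485 and 2728) and 5462 for SAS against HSC4 (2641 and 2821).

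MAGEA4 had a mean CPM of 83.2 in HSC3, 0 in HSC4 and 1.04 in SAS (edgeR adjusted p = 0.000257 for the contrast with SAS). AKR1C1 had a mean of 85.1 CPM in HSC3 (34.3 and 136 in its 2 libraries) against 1.35 in HSC4 and 0.32 in SAS, and AKR1C2 had 61.1 (11.5 and 111) against 0.571 and 0.266, with the split between these paralogs uncertain. The pseudogene KRT16P6 had 29.4 CPM in HSC3 against 0.27 and 0.428. In HSC4, TNNT3 had 147 CPM (114 and 181) against 0.836 in HSC3 and 3.28 in SAS, C15orf48 40.4 (25.7 and 55.2) against 0.284 and 0.822, C3orf14 37.1 against 0.595 and 0.0796, and the pseudogene NOP56P3 23.9 against 0.568 and 0. In SAS, KRTAP2-3 had 366 CPM (124 and 608) against 4.88 in HSC3 and 1.89 in HSC4, KLK6 240 against 4.31 and 4.39, IGFL1 89.9 against 0.415 and 0.779, and HSD11B1 20.1 (10.6 and 29.7) against 0.308 and 0.24. All 12 passed in both contrasts of their line, as the rule for naming them required. Without the DMEM library of HSC4 the AKR1C2 call ended, with a smallest log2 fold change over the other lines of 5.13.

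Members of the fixed lists were counted by the line with their highest level, with no test of the lists themselves. Of 23 interferon-stimulated genes tested, 20 differed between lines by the edgeR F-test, and 18 of these had their highest level in HSC4. Of 20 NF-kB genes 15 differed, 11 of them highest in HSC4 and 0 in SAS. Of 21 NRF2 targets 19 differed, 13 of them highest in HSC3. All 21 basal epithelial genes differed, 10 highest in HSC3, 10 in HSC4 and 1 in SAS. Of 35 ribosomal protein genes 28 differed, 18 of them highest in SAS, and of 25 cholesterol synthesis genes 18 differed, 11 of them highest in SAS. Of 14 class I antigen presentation genes 13 differed, 8 of them highest in HSC4, 5 in HSC3 and 0 in SAS. Lists below the share over all genes included the unfolded protein response, with 5 of 17 genes that differed, mitochondrial-encoded genes with 5 of 13, mitotic genes with 10 of 24 and iron homeostasis with 4 of 9.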

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

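The tests of XAB2, of the splits of the libraries and of the gain in leukocyte genes between media were chosen after the results they bear on were seen. The differences between lines given next were not tested; with 1 library per line and medium, a full interaction of line and medium leaves no residual degrees of freedom.

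Among lists with 5 or more tested genes, the medians of 4 were at least 0.2 above 0 in 1 line and at least 0.2 below 0 in another. Of the smaller lists, the fibroblast markers (0.34 in HSC4, −0.75 in SAS) and the endothelial markers (0.43 in HSC4, −0.46 in SAS) also lay so. For the ATF4 list the medians were −0.70 in HSC3, 0.15 in HSC4 and 0.21 in SAS, a range of 0.91. For metallothioneins they were 0.60, 0.14 and −0.30, a range of 0.90. For genes encoded in mitochondrial DNA they were −0.30, 0.04 and 0.33, a range of 0.63. For mitotic genes they were 0.24, −0.24 and −0.07, a range of 0.48.

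The NF-kB and keratinocyte differentiation lists stood highest in HPLM. Removing a trend with transcript length within each line left the mean of the line medians at 1.02 (1.04 before) for the NF-kB list and at 0.91 (0.98 before) for the keratinocyte list, both with camera adjusted p = 3.54e-19 at the preset correlation, which argues against such a trend as the whole source. With an estimated correlation neither list passed before the removal (camera adjusted p = 0.45 and 0.44). Leukocytes were to be excluded if PTPRC, TYROBP and LYZ together lay under 1 CPM, and this bound was not met, since PTPRC alone lay between 1.61 and 2.24 CPM in both media and the highest sum in HPLM was 2.19 CPM; in the test of the gain, however, the sum rose by at most 0.39% of the rise of S100A8 and S100A9 in a line, which argues against leukocytes as the source of that rise. The real split of the 6 libraries called 18 lists, the other 3 splits that part every pair 12, 8 and 12, and the 6 that part 1 pair, which are 3 fits each counted 2 times and rest on that pair, at most 14; 1 of the 10 splits, the real one itself, gave 18, and neither the 10 nor the 4 that part every pair are enough for a share under 0.05. A response to the medium, culture density or time in culture may each underlie the pattern, and none of these was tested. A technical difference between the DMEM and the HPLM libraries could not be told apart from them in this design.

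Ribosomal protein and respiratory chain genes were slightly higher in HPLM. With the length trend removed, the mean of the line medians of the ribosomal protein list went from 0.17 ± 0.12 to 0.08 ± 0.11 (SD, 3 lines) and its camera adjusted p from 1.43e-06 to 0.0269. For the respiratory chain list the mean went from 0.11 ± 0.02 to 0.07 ± 0.07 and the adjusted p from 0.000672 to 0.0422. These p-values rest on the preset correlation, and with an estimated one neither list passed before the removal (camera adjusted p = 0.45 for each). The part removed was 0.090 ± 0.035 and 0.044 ± 0.050, so a trend with length, to which these short transcripts would be prone, and a response to the medium cannot be told apart.

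XAB2, the 1 gene past the threshold, rested on 1 of its 4 transcripts, at 0.70, 1.01 and 2.34 CPM in DMEM and 10.3, 12.3 and 28.8 CPM in HPLM. The loss of the other XAB2 transcripts came to −0.3% ± 1.8 (SD, 3 lines) of that gain, where a negative value is a rise. The call was made on the sum of the 4 transcripts, and a loss near the gain could not go with it. This value is therefore no check of the call. The 3 genes within 5 kb gave a loss of −139.1% ± 220.9, a spread that decides nothing. Transcripts that changed at least 8-fold in 1 direction in all 3 pairs numbered 101 in the real split and 67, 86 and 93 in the other 3 splits that part every pair, so noise in the estimates of single transcripts remains a candidate explanation. By edgeR the real split called 1 gene (1339 at an unadjusted p under 0.05, smallest p 3.6e-06), the other 3 that part every pair 0 (332, 399 and 316, smallest p 6.8e-05, 0.00089 and 9.8e-05) and those that part 1 pair 0 (at most 756, smallest p 4.3e-06); 1 of the 10 splits, the real one itself, called a gene, and the splits are again too few for a share under 0.05.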

How the results depend on the processing

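Leaving out mitochondrial-encoded genes, keeping protein-coding genes alone, and leaving a line out of the values per line were chosen after seeing the data. Of 119 named genes, 115 kept their direction in all alternatives run, and 11 of 12 genes named for a line kept their call. Apart from the genes named whatever their values, the medium genes were mostly taken for a small p. The first of them also had to share a direction in all lines. The genes named for a line were taken for the largest called differences. Selection therefore favoured both counts, and they are no check of the named genes. The medium comparison called 1 gene. By edgeR it called 0 with no replicate block (59 genes at an unadjusted p under 0.05), 0 with upper-quartile scaling (1339) and 0 with no low-count filter (1504), by limma-trend 0 (1384), by limma-voom 9 and by DESeq2 127, and leaving out a line gave 0 (1101 without HSC4, 1052 without SAS) to 4 (without HSC3). The other alternatives gave 1. With no replicate block the lists of glucose sensing (camera adjusted p = 0.109), class I antigen presentation (0.172), S phase (0.101) and arginine metabolism (0.0854) lost their call, and the block changed no other list call. Of 36 lists, 18 passed by camera, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 0 by directional fry (7), and the other list counts lay between 12 and 21. Counts between lines lay between 5715 and 7945. Changes of 2-fold were missed in part in the simulations of the medium comparison. There 88.1% were called, and 40.3% where the spread varied between genes.

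Genes 2-fold changed in all lines numbered 16, with 39 at a mean CPM of 1 or more, 9 at 20 or more and 38 to 49 without a line, where fewer lines are asked. The mean r between lines was 0.152, with 0.123 at a prior count of 0.5, 0.258 at a mean CPM of 5 or more, 0.304 at 20 or more and 0.131 to 0.173 without a line.

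Directions turned as follows, and the cause was not tested. With no replicate block VIM had 0.007 and the endothelial list 0.007, and with no low-count filter the fibroblast list had 0.253. Leaving out each line gave log2 fold changes from −1.322 to 0.454 for the gene ASNS, −0.046 to 0.364 for the gene CDH1 and −0.627 to 0.223 for the gene ERG. List means ran from −0.406 to 0.329 for ATF4, −0.07 to 0.073 for aminoacyl-tRNA synthetases, −0.062 to 0.093 for p53, −0.074 to 0.189 for mitochondrial-encoded, −0.163 to 0.059 for mitotic, −0.048 to 0.163 for MYC, −0.169 to 0.042 for mesenchymal, −0.119 to 0.094 for basal epithelial, −0.423 to 0.074 for fibroblast and −0.214 to 0.489 for endothelial genes.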

Other observations

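Genes that keratinocytes are known to induce on stimulation by IL-17 or IL-1, outside the fixed lists, were chosen as 14 genes before their values were seen, to ask whether they move with the inflammatory genes. Of the 8 tested, 7 had a positive log2 fold change in HPLM, with a median of 1.19. C3, the central complement gene, had 1.48 ± 0.39 (SE, edgeR adjusted p = 0.381), S100A12 1.93 ± 0.68, the NF-kB inhibitor gene TNIP1 0.55 ± 0.19, the protease inhibitor gene SLPI 0.56 ± 0.21 and IL1RN −0.32 ± 0.31. The line medians were 2.10 in HSC3, 0.26 in HSC4 and 0.18 in SAS, and 2 genes were higher in all 3 lines. Camera gave p = 3.9e-05 with a preset correlation and p = 0.067 with an estimated correlation of 0.05. The hypothesis, for which a p under 0.05 in the second form had been set, therefore remained undecided. In SAS, C3 had a log2 ratio of 2.28, SERPINB3 1.83, TNIP1 0.76 and IL1RN 0.36. CXCL6, S100A12 and SLPI lay there at 0, −0.01 and 0, and IL36G at −1.47. The rise was thus not confined to HSC3, and the difference between lines was not tested.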
